A study of Homo sapiens with 22 samples.

How the data were processed

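RNA was sequenced from 22 samples of MCF-7 cells. Per the labels, the cells were kept for 3 days in medium with charcoal-stripped serum, which holds little steroid hormone, and then treated for 3 days with 0.1% DMSO, 10 nM E2, 10 µg/ml of a soymilk extract or 10 µM of an isoflavone. Libraries were made with the TruSeq Stranded mRNA kit and an MGIEasy conversion kit. The authors' notes name cutadapt 2.10, HISAT2 2.2.1, Cuffdiff 2.2.1 and the hg19 build, without saying what each tool was used for or which annotation was used.

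The authors deposited 11 tables of 26237 entries, with a single value per gene symbol in each: 1 table for each E2 replicate and 1 for each other treatment. The unit of every deposited column is named "other" here, because it holds log2 ratios to the DMSO control, made by the authors, beside spreadsheet division and number errors, which fill 42.0% to 43.8% of the cells. The digits of the values show how the ratios were formed. In each E2 table, 2 to the power of the value was a ratio of 2 numbers of 6 significant digits for 60 of 60 genes sampled, against 0 or 1 of 60 with base e or base 10. In each other table, the squared ratio times the square of the control's digits from E2 replicate 1 was a product of 2 such numbers for 64 of 64 genes, against 0 to 2 of 64 with a wrong control and 0 for an arithmetic mean or a single number. The 8 treatment values are therefore read as means of the log2 ratios of 2 libraries to 1 control library, the one used for E2 replicate 1. Across these 9 columns, 9702 entries had the error of a control at 0, the same entries in each, against 9947 and 10379 in E2 replicates 2 and 3. The labels do not say which control sample this is. Expression levels, counts and, for treatments other than E2, values of single libraries were not used here, since the tables hold none. The depth of each library and the precision it gives are therefore unknown. The number of libraries limits the precision: 3 ratios for E2, and 1 pooled value for each other treatment.

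Cells with an error were left out gene by gene, as were 28 entries whose gene symbol a spreadsheet had turned into a date. Of 26209 symbols, 23676 were current in the annotation, 1432 were older symbols of current genes and 1101 were not found. No coordinates are given, because the reference annotation is for another build. No filter on expression and no pseudocount were applied, since the tables give ratios alone.

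For E2, limma 3.58.1 in R 4.3.3 tested the 3 log2 ratios of 14240 genes against 0, with moderated variances without a trend on expression level, and Benjamini-Hochberg adjustment at 0.05. The median moderated SD of 1 ratio was 0.195. For the other treatments and the 7 differences between them, genes at or past 2-fold (a log2 ratio of 1) were counted, which is not a test. A borrowed-spread t-test was added after the data were seen, for all genes and, adjusted over 11 genes, for those named in advance. It set each pooled value or difference against the moderated variance and degrees of freedom of the limma fit to E2, and limma was not fitted to the pooled values themselves. It took the variance of a treatment value as 0.75, of a difference between treatments as 0.5 and of a difference of differences as 1 times that of an E2 ratio, from the number of libraries in each, and assumed that other libraries vary like those of E2. Its 95% intervals rest on the same assumption.

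The 27 gene lists were fixed before the data were examined, with 611 of 612 members in the tables. For E2 they were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance or, in its mixed form, at all. With an estimated correlation, camera uses the few residual degrees of freedom, so its p can rise without correlation between genes. For the other tables the median over the members with a ratio in all 11 tables was set against 10000 random lists of the same size, matched on the moderated spread in 10 bins in place of expression level, which was not given. Similarity to E2 was measured as Pearson's r and Spearman's rho across genes, and as the share of genes past 2-fold in E2 replicates 2 and 3 that were past it in another table. Simulations in which neither the treatments nor E2 had an effect (100 runs) gave the r that the shared control produces between unchanged groups. A gene symbol of the form A-B whose parts are both gene symbols in the tables was taken as a readthrough symbol (71 of them).

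The genes named were set in advance. For E2 they were the 10 highest and 10 lowest among called genes with the same sign in all 3 ratios, and the members of the estrogen-induced and estrogen-repressed lists. For each other treatment and difference they were the 5 highest and 5 lowest, by size alone. Symbols of unnamed loci, long intergenic, small nuclear and small nucleolar RNAs, microRNAs and ribosomal RNAs were left out of these rankings, such as LOC101929829 at 14.41 with fermented black. TFF1, PGR, GREB1, PDZK1, CXCL12, MYC, CCND1, ESR1, ERBB2, CYP1A1 and CYP1B1 were named throughout, with the highest and lowest members of lists as examples. Alternatives changed the fold threshold (1.5 and 3), the adjusted p (0.01 and 0.1), the centring of each table (on the median of all genes, or of the reference genes list), the E2 replicates used, the correlation, the genes used, the handling of repeated and date-like symbols, and the mean in place of the median of a list. The comparison of the 4 isoflavone with the 4 extract tables, fitted with limma to 13852 genes, was added after the data were seen.

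The methods were tested on simulated data with 50 genes changed at each size. The E2 test recovered 4% of genes changed by 1.5-fold, 52% at 2-fold, 96% at 4-fold and 100% at 8-fold. The borrowed-spread test of 1 treatment recovered 4% at 2-fold and 78% at 4-fold, that of a difference 18% and 92%, and the comparison of isoflavones with extracts 78% and 94%. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.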

Results

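The study measured gene expression by RNA sequencing in MCF-7 cells, an estrogen receptor-positive human breast cancer cell line, to ask how far soymilk extracts and soy isoflavones act like estrogen. The 22 samples formed 10 groups, with 3 samples of the vehicle control (0.1% DMSO), 3 samples treated with 10 nM 17β-estradiol (E2), and 2 samples for each of the other 8 treatments. Those were extracts of unfermented or fermented soymilk from yellow or black soybeans at 10 µg/ml, and the isoflavones genistin, genistein, daidzin and daidzein at 10 µM. Genistin and daidzin are the glucosides of the aglycones genistein and daidzein. Each value was a log2 ratio of a treated sample to the control, 1 for each E2 sample and 1 mean over both samples for each other treatment, so a spread between replicates can be given for E2 alone. The 26209 gene symbols included 16316 with a ratio in at least 1 table and 13733 with a ratio in all 11 tables. Read totals, expression levels and counts were not among the values, so the depth of each sample is unknown and no counting interval can be given. Genome positions are not given, because the authors' build (hg19) differs from that of the annotation used here.

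The E2 comparison asked which genes respond to estrogen in these cells. Known estrogen receptor targets rose strongly: TFF1, a secreted trefoil peptide, had a log2 ratio of 2.71 ± 0.34 (SD, n = 3, adjusted p = 0.0255) and GREB1, a cofactor of the receptor, 2.68 ± 0.25 (adjusted p = 0.0241). PGR, the progesterone receptor gene, rose by 1.67 ± 0.26 (adjusted p = 0.0278) and the scaffold gene PDZK1 by 2.37 ± 0.49 (adjusted p = 0.0314). ESR1, which encodes the estrogen receptor alpha, fell by 0.82 ± 0.17 (adjusted p = 0.0462). CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, had a ratio of -3.43 ± 0.70 (adjusted p = 0.0302). CXCL12 at 0.65 ± 0.29, CCND1 at 0.46 ± 0.09, MYC at -0.26 ± 0.09, ERBB2 at -0.12 ± 0.03 and CYP1B1 at -0.13 ± 0.39 did not pass the test (adjusted p from 0.0733 to 0.696).

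Across all 14240 genes with a ratio in the 3 E2 tables, 351 were higher and 322 lower at an adjusted p of 0.05, each with the same sign in all 3. The 10 named genes that rose most were B3GNT6, PADI3, IL24, SLC5A8, TUBA3E, KIAA0125, TACR1, MGAT3, TUBA3D and KLK12. The first of them, the glycosyltransferase gene B3GNT6, had a log2 ratio of 4.84 ± 0.16 (28.6-fold, SD, n = 3, adjusted p = 0.0126). The last, the kallikrein gene KLK12, had 3.22 ± 0.31 (adjusted p = 0.0241). The 10 that fell most were RPL21, KL, APOL3, CYP1A1, VTN, CRISP3, CEMIP, DIO1, PLCE1 and PMP22. Below RPL21, they ran from KL, the klotho gene, at -3.81 ± 0.77 (adjusted p = 0.0293) to PMP22, a myelin protein gene, at -3.23 ± 0.40 (adjusted p = 0.0255). RPL21, a ribosomal protein gene with many pseudogene copies, had -11.93 ± 0.20 (adjusted p = 0.00114), and its ratios in other tables ran from -11.71 with genistein to 1.15 with daidzein. The calls needed all 3 E2 replicates: limma on 2 of them called 0 genes without replicate 1, 1 without replicate 2 and 0 without replicate 3, with 3278, 2545 and 2819 genes at an unadjusted p under 0.05. Centred on the reference genes, whose median ratio was 0.07 to 0.36 over the 11 tables, the split of 351 higher and 322 lower became 251 higher and 623 lower.

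Estrogen-induced genes were higher with E2. Of the 44 tested members of that list, 22 rose and 0 fell, or 37 and 3 when adjusted over the list alone, with a median log2 ratio of 0.98 (camera adjusted p = 3.36e-16, adjusted p = 0.379 with an estimated correlation). The estimate was 0.0117, close to the preset 0.01, so the higher p does not come from correlation between these genes. CTSD, the cathepsin D gene, rose by 1.92 ± 0.09 (SD, n = 3) and SUSD3 by 2.29 ± 0.45, while KCNK5 at -0.88 ± 0.25 and STC2 at -0.62 ± 0.19 did not pass over all genes. Of the 21 estrogen-repressed genes, 7 fell and 0 rose, or 16 and 1 when adjusted over the list alone, with a median of -0.82 (adjusted p = 5.73e-10, adjusted p = 0.47 with an estimated correlation). The interleukin receptor gene IL1R1 fell by 3.13 ± 0.20 and TGFB3 by 1.86 ± 0.49. The highest member, SEMA6A at 0.73 ± 0.37, did not pass over all genes.

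Cell cycle genes were higher with E2. The median over 33 G2/M and mitosis genes was 0.59, with 4 genes that rose and 0 that fell, or 31 and 0 when adjusted over the list alone (camera adjusted p = 2.16e-13, adjusted p = 0.655 with an estimated correlation). AURKB, a mitotic kinase gene, rose by 0.96 ± 0.12 (SD, n = 3). The median over 35 DNA replication and G1/S genes was 0.54, with 2 that rose and 0 that fell, or 28 and 1 when adjusted over the list alone (adjusted p = 2.34e-10, adjusted p = 0.749 with an estimated correlation). Fry's test did not pass for either list (adjusted p = 0.0551 for G2/M and 0.101 for G1/S). TK1, the thymidine kinase gene, rose by 0.64 ± 0.09, and CCNE1 had -0.40 ± 0.09, which did not pass over all genes. In the hypoxia and glycolysis list 12 of 21 genes rose and 0 fell, or 15 and 2 when adjusted over the list alone, with a median of 0.90 (adjusted p = 2.04e-06, adjusted p = 0.655 with an estimated correlation). ALDOC, LDHA and PGK1, which encode glycolytic enzymes, rose by 1.62 ± 0.51, 1.08 ± 0.19 and 0.95 ± 0.04. The lowest members of that list, EGLN3 at -0.35 ± 0.32 and HILPDA at -0.35 ± 0.07, did not pass over all genes.

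Interferon response genes were lower with E2. Of 28 tested, 11 fell and 0 rose, or 18 and 1 when adjusted over the list alone, with a median of -0.88 (camera adjusted p = 8.76e-08, adjusted p = 0.385 with an estimated correlation). The estimate was 0.00774, below the preset 0.01, so here too the higher p does not come from correlation. OAS2, an antiviral enzyme gene, fell by 2.59 ± 0.80 (SD, n = 3) and IFI44 by 1.73 ± 0.31. The highest member, HERC6 at 0.54 ± 0.33, did not pass over all genes. In the immediate-early list 1 of 20 genes rose and 2 fell, or 1 and 8 when adjusted over the list alone, with a median of -0.56 (adjusted p = 0.000371, adjusted p = 0.647 with an estimated correlation). CTGF fell by 2.99 ± 0.39 and FOSB by 2.44 ± 0.43, and EGR3 rose by 2.16 ± 0.63. Of 14 BCL2 family genes 3 fell and 0 rose, or 4 and 0 when adjusted over the list alone, with a median of -0.24, or -0.39 when centred on the reference genes (adjusted p = 0.0129, adjusted p = 0.631 with an estimated correlation), and the pro-apoptotic gene BMF fell by 1.82 ± 0.33. The 23 cholesterol synthesis genes had a median of 0.53 (adjusted p = 0.00336, adjusted p = 0.765 with an estimated correlation), with none called over all genes or when adjusted over the list alone, and replicate medians of 0.88, 0.68 and -0.17. Correlation was estimated at 0.773 for cholesterol synthesis and 0.121 for immediate-early genes, above the preset 0.01, so their camera p at that setting can be too low. Of 6 tested leukocyte marker genes 1 rose, CD68 by 1.40 ± 0.26, or 2 when adjusted over the list alone (median 0.78, adjusted p = 0.0331, adjusted p = 0.647 with an estimated correlation). CD68 is a lysosomal gene that epithelial cells also express. Without E2 replicate 1 the calls of the cholesterol synthesis (adjusted p = 0.0905), BCL2 family (adjusted p = 0.0905) and leukocyte marker (adjusted p = 0.154) lists were lost.

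**Figure D1:**
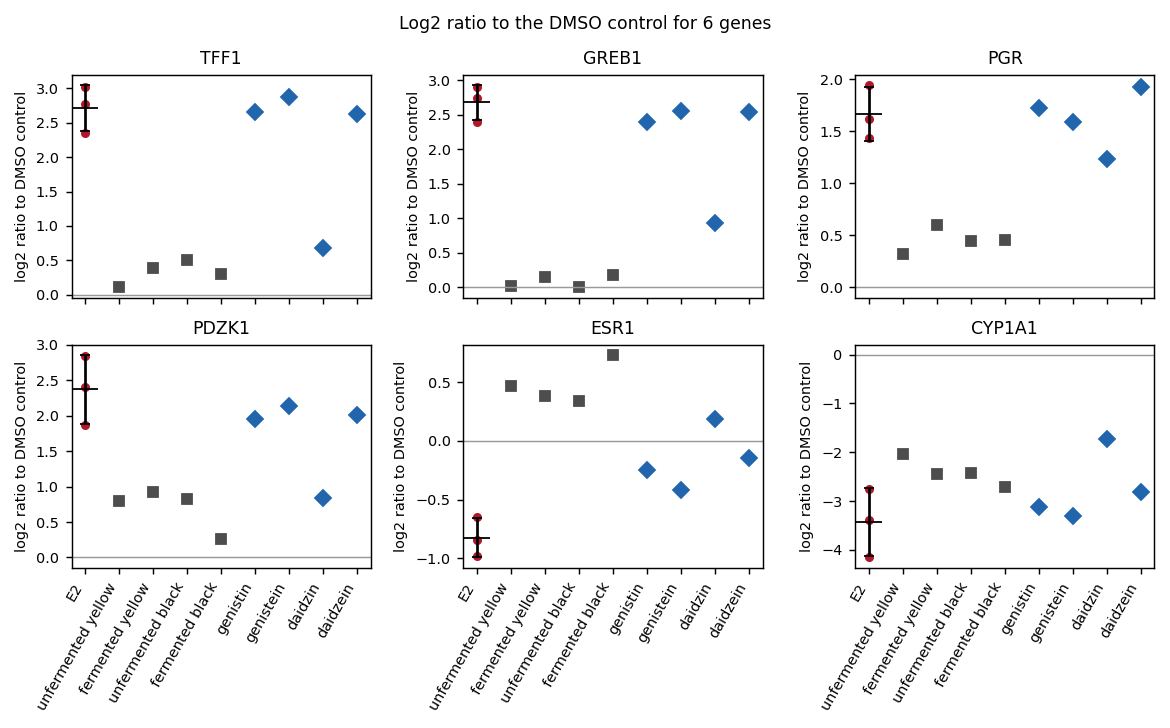
Log2 ratio to the DMSO control (vertical axis) of TFF1, GREB1, PGR, PDZK1, ESR1 and CYP1A1 in each treatment (horizontal axis). Dots are the 3 E2 replicates with their mean and SD, squares are the extracts and diamonds the isoflavones, each the authors' mean over 2 samples; TFF1 stands between 2.62 and 2.87 with genistin, genistein and daidzein, at 0.68 with daidzin, and between 0.11 and 0.50 with the extracts.

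The isoflavone comparisons asked whether each compound acts like estrogen. Genistin, genistein and daidzein gave large ratios for the estrogen receptor targets. TFF1 had a log2 ratio of 2.66 with genistin, 2.87 with genistein and 2.62 with daidzein, GREB1 had 2.40, 2.56 and 2.55, PGR had 1.72, 1.59 and 1.92, and PDZK1 had 1.95, 2.14 and 2.01. With daidzin the ratios were 0.68 for TFF1, 0.92 for GREB1, 1.24 for PGR and 0.83 for PDZK1. Among the 44 estrogen-induced genes, 21 were at least 2-fold higher with genistin, 23 with genistein, 25 with daidzein and 4 with daidzin, and the list medians were 0.97, 1.04, 1.03 and 0.51. The estrogen-repressed list had medians of -0.72, -0.85, -0.92 and -0.43 in the same order. CYP1A1 stood at -3.13 with genistin, -3.31 with genistein, -1.74 with daidzin and -2.82 with daidzein, and CXCL12 at 1.06, 0.79, 0.82 and 1.12. ESR1 stayed between -0.41 and 0.19, ERBB2 between -0.48 and -0.25, CCND1 between 0.41 and 0.73, MYC between -0.10 and 0.35, and CYP1B1 between -0.47 and 0.02 over the 4 isoflavones. With the E2 spread borrowed and p adjusted over the 11 genes named in advance, limma called TFF1, GREB1, PGR and PDZK1 with genistin, genistein and daidzein (adjusted p from 0.00188 to 0.0095) and PGR alone of these with daidzin (adjusted p = 0.0424, against 0.0506 for GREB1, 0.0801 for TFF1 and 0.0801 for PDZK1). It also called CYP1A1 and CXCL12 with genistin, genistein and daidzein (adjusted p from 0.00575 to 0.0347), CCND1 with genistein (0.0108) and daidzein (0.0234), and ERBB2 with genistin (0.0314) and daidzein (0.0234). Centring on the reference genes, which lowers every value by 0.26 with genistin, 0.31 with genistein, 0.16 with daidzin and 0.32 with daidzein, turned the sign of MYC with genistin and genistein and of CYP1B1 with daidzein. Called values such as those of CCND1 and CXCL12 shift by the same amounts, and the borrowed-spread test was not rerun with that centring.

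Other gene groups also stood away from 0 with the isoflavones. The interferon response list had medians of -1.65 with genistin, -1.69 with genistein, -1.03 with daidzin and -1.75 with daidzein. IFI44 was lowest with genistin at -3.58, and the highest members in that table were UBE2L6 at -0.04 and USP18 at 0.36. The cholesterol synthesis medians were 1.33, 0.99, 0.92 and 1.46, with STARD4, a sterol carrier gene, at 2.48, 2.68, 1.54 and 2.94 and SC5D at 0.03, 0.12, -0.12 and 0.28. The DNA replication and G1/S medians were 0.91, 0.95, 0.86 and 1.12, with RRM2, a ribonucleotide reductase gene, at 1.58, 1.83, 1.13 and 1.81 and CCNE1 at -0.47, -0.16, 0.18 and -0.11. The G2/M and mitosis medians were 0.96, 0.99, 0.62 and 1.20. Against 10000 random lists of the same size, those cell cycle and cholesterol medians stood at percentile 100 and the interferon medians at percentile 0 in each of the 4 tables. Random lists leave out correlation between members. From the E2 ratios it was estimated at 0.791 for G1/S, 0.581 for G2/M, 0.773 for cholesterol synthesis and 0.00774 for interferon response genes. The 4 tables also share 1 control library, so these percentiles do not test the lists independently.

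By size alone, 655 genes were at least 2-fold higher and 1025 lower with genistin, 869 and 1038 with genistein, 411 and 659 with daidzin, and 762 and 1123 with daidzein. Centred on the reference genes, the percentage of these genes that were higher went from 39.0 to 20.3 with genistin, from 45.6 to 22.6 with genistein, from 38.4 to 23.2 with daidzin and from 40.4 to 17.7 with daidzein. B3GNT6 was among the 5 highest genes with genistin at 5.40, genistein at 5.65 and daidzein at 5.33. Other extremes among named genes included overlapping or multi-copy loci, with TNXB at 9.26 highest and the readthrough symbol C1QTNF3-AMACR at -12.27 lowest with daidzin, FAM72D at 11.42 and the histone gene HIST1H2AD at -12.51 with daidzein, and PMS2P2 at 12.74 and PHOSPHO2-KLHL23 at -9.35 with genistin. With genistein the neighbours KIAA0408 and SOGA3 were highest at 13.49 and lowest at -15.13. A 2-fold size is not a test. With the spread of the E2 replicates borrowed for the pooled values, limma called 2 genes in each of the 4 isoflavone tables (B3GNT6 with genistin, genistein and daidzein, and the multi-copy loci RGPD6 with genistin, daidzin and daidzein and RPL21 with genistein and daidzin), with 1749 to 3365 genes at an unadjusted p under 0.05.

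The extract comparisons asked the same question of the soymilks. Over the unfermented yellow, fermented yellow, unfermented black and fermented black extracts TFF1 had log2 ratios of 0.11, 0.38, 0.50 and 0.31, PGR 0.32, 0.60, 0.44 and 0.46, and PDZK1 0.80, 0.92, 0.82 and 0.26. GREB1 had 0.02, 0.14, 0.00 and 0.17. Centred on the reference genes, GREB1 turned below 0 with unfermented yellow, fermented yellow and fermented black, and TFF1 and PGR with unfermented yellow. Of the 44 estrogen-induced genes, 2, 3, 2 and 2 were at least 2-fold higher in that order. Their medians were 0.28, 0.34, 0.27 and 0.21, at percentile 99.95 to 100 of random lists, with 35, 37, 36 and 31 genes above 0, and stood below 0 with that centring, which lowers every value of a table by 0.36, 0.36, 0.35 and 0.24. The estrogen-repressed medians were -0.59, -0.61, -0.55 and -0.31, at percentile 0 to 0.02, and -0.95, -0.97, -0.90 and -0.55 with that centring. ESR1 was at 0.46, 0.39, 0.34 and 0.73, MYC at 0.38, 1.09, 0.96 and 1.15, CXCL12 at 0.74, 0.82, 0.87 and 0.76, and CYP1A1 at -2.04, -2.45, -2.43 and -2.71. CCND1 at 0.32, 0.34, 0.21 and 0.17 also turned sign with that centring in all 4, and ESR1 did so with unfermented black. ERBB2 stayed between -0.34 and -0.01 and CYP1B1 between -1.28 and -0.57. Adjusted over the 11 genes, limma with the borrowed spread called MYC and CYP1A1 with fermented yellow, unfermented black and fermented black (adjusted p from 0.012 to 0.0348), ESR1 and CYP1B1 with fermented black (adjusted p = 0.0292), and none with unfermented yellow, where CYP1A1 had the lowest adjusted p at 0.126.

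Cell cycle and sterol genes stood high with the extracts. The DNA replication and G1/S medians were 1.07, 1.12, 1.06 and 0.74 in the same order, with 21, 23, 22 and 6 of 35 genes at least 2-fold higher, and TK1 stood at 1.63, 1.53, 1.57 and 1.18. The G2/M and mitosis medians were 0.99, 1.15, 1.13 and 0.92. The cholesterol synthesis medians were 1.32, 1.23, 1.53 and 0.76, with 17, 17, 19 and 5 of 23 genes at least 2-fold higher, and MVK, the mevalonate kinase gene, stood at 2.06, 2.03, 2.37 and 1.46. Interferon response genes stood low, with medians of -1.21, -1.23, -1.19 and -0.50 and IFI27 at -2.91, -2.48, -3.09 and -1.10, while UBE2L6 stood at 0.54, 0.35, 0.50 and 0.36. The 8 basal and myoepithelial markers were all below 0 in each table, with medians of -0.75, -0.90, -1.09 and -0.59. The 6 fibroblast markers had medians of -0.62, -0.71, -1.09 and 0.18, the last of them -0.06 when centred on the reference genes. That centring lowers every median of this paragraph by 0.36, 0.36, 0.35 and 0.24 in the same order. All 8 treatment tables were ratios to 1 control library, so these medians are not independent between tables.

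Genes at least 2-fold higher and lower numbered 465 and 1257 with unfermented yellow, 511 and 1375 with fermented yellow, 497 and 1447 with unfermented black, and 434 and 832 with fermented black. Centred on the reference genes, the percentage higher went from 27.0 to 8.67, from 27.1 to 8.33, from 25.6 to 8.36 and from 34.3 to 16.2. The highest and lowest named genes, with unnamed loci left out, were TNXB at 8.43 and INO80B-WBP1 at -11.10 with unfermented yellow, C8orf44-SGK3 at 9.39 and INO80B-WBP1 at -12.16 with fermented yellow, C8orf44-SGK3 at 7.27 and INO80B-WBP1 at -12.60 with unfermented black, and PMS2P2 at 12.78 and PHOSPHO2-KLHL23 at -12.20 with fermented black. Of these, all but TNXB and PMS2P2 are readthrough symbols, which join neighbouring genes. On the 14240 genes tested for E2, 955 to 1666 were past 2-fold with the extracts and 798 to 1612 with the isoflavones. Differences between E2 replicates, scaled to the same number of libraries, put 504 to 543 there. With the borrowed spread, limma called 0 genes for each yellow extract, 2 readthrough symbols for unfermented black and 3 multi-copy loci (NPIPA8, RGPD6 and RPL21) for fermented black, with 3058, 3328, 3788 and 2017 genes at an unadjusted p under 0.05.

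**Figure D2:**
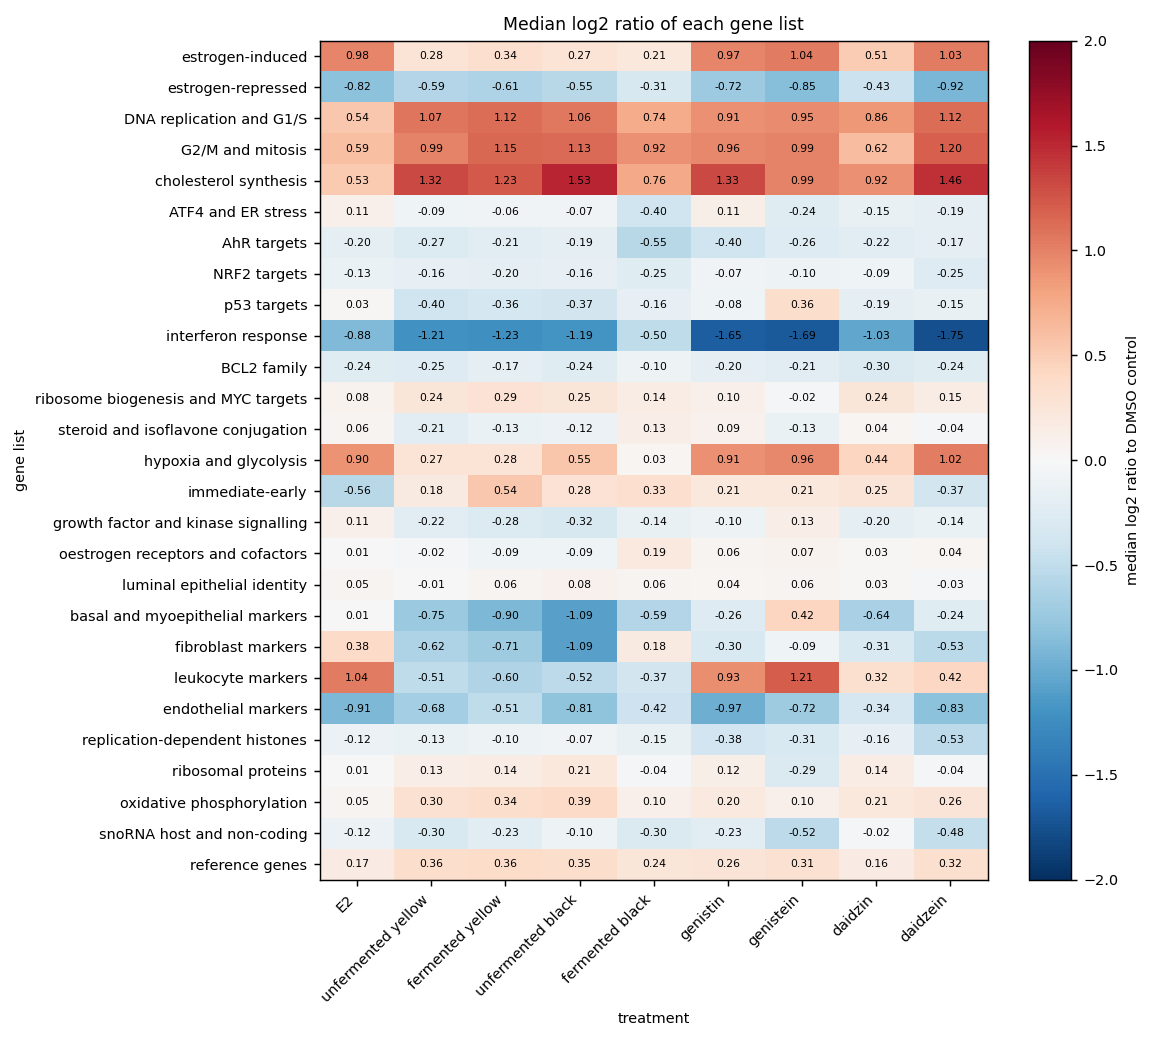
Median log2 ratio to the DMSO control of each of 27 gene lists (vertical axis) in each treatment (horizontal axis), over the members with a ratio in every table, with E2 as the mean of 3 replicates. The estrogen-induced median stands at 0.98 with E2, 0.51 to 1.04 with the isoflavones and 0.21 to 0.34 with the extracts, where it falls below 0 when centred on the reference genes; the G1/S median stands between 0.74 and 1.12 in all 8 other treatments.

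The similarity of each treatment to E2 asked how much of the whole response was shared. The 540 genes that were at least 2-fold the same way in E2 replicates 2 and 3 (280 higher and 260 lower) were followed in tables made against a different control. In E2 replicate 1, 63.2% of the higher and 69.6% of the lower genes were again past 2-fold the same way. With genistein 65.0% and 71.9% were, with daidzein 54.6% and 72.7%, with genistin 51.4% and 71.9%, and with daidzin 18.2% and 30%. With the extracts 9.64% to 12.1% of the higher and 19.6% to 36.5% of the lower genes were, against 2.16% to 3.01% and 3.62% to 8.03% of all genes. The share of all genes was not matched on spread. The median ratio of the 280 higher genes was -0.08 to 0.03 with the extracts and 0.39 to 1.28 with the isoflavones, so these genes did not rise on balance with the extracts. The median of the 260 lower genes was -0.68 to -0.30 with the extracts and -1.48 to -0.68 with the isoflavones. SLC5A8, a monocarboxylate transporter gene that rose by 4.06 with E2, stood at 3.06 with genistin and 3.51 with genistein but between -0.47 and 0.09 with the extracts, and CRISP3 at -2.96 and -3.02 but between -0.10 and 0.31. Over all 4 isoflavones the mean was 2.73 (SD 1.22) for SLC5A8 and -2.66 (SD 0.653) for CRISP3. In the opposite direction, 45 to 56 of the 540 genes were past 2-fold with the extracts and 6 to 16 with the isoflavones.

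Across 13733 genes, which are not independent replicates, Pearson's r with the mean of the 3 E2 tables was 0.663 for genistin, 0.667 for genistein, 0.663 for daidzein, 0.451 for daidzin and 0.215 to 0.247 for the extracts. In simulations where neither the treatments nor E2 had an effect, the shared control gave a mean r of 0.331. Real E2 ratios hold large changes, so this value is not a bound for the r above. The covariance with the mean of the 3 E2 tables was 0.0135 to 0.0286 in the simulations and 0.0622 to 0.0863 for the extracts. To avoid the shared control, r was also taken with E2 replicates 2 and 3. It was then 0.553, 0.572, 0.553, 0.339 and 0.129 to 0.165 in that order, against simulated values of -0.162 to 0.119. The simulations drew each gene independently, so correlation between real genes can give wider ranges of r and of the covariance. The extract values just above 0.119 therefore do not exclude chance. With E2 replicate 3 alone r was 0.0456 to 0.0649 for the extracts. Within the 44 estrogen-induced genes r with the mean of 3 was 0.93 for genistin, 0.90 for genistein, 0.92 for daidzein, 0.47 for daidzin and -0.26 to -0.01 for the extracts, and within the 21 estrogen-repressed genes it was 0.90, 0.80, 0.89, 0.50 and 0.07 to 0.44. On the same 13733 genes the E2 tables agreed at r of 0.505 to 0.537 between pairs, and E2 replicate 1 had 0.589 with the mean of replicates 2 and 3. Across 14240 genes the pairs had 0.449 to 0.465 (Spearman's rho 0.459 to 0.556), and 87.5% to 88.5% of the genes past 2-fold in both tables of a pair had the same direction.

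**Figure D3:**
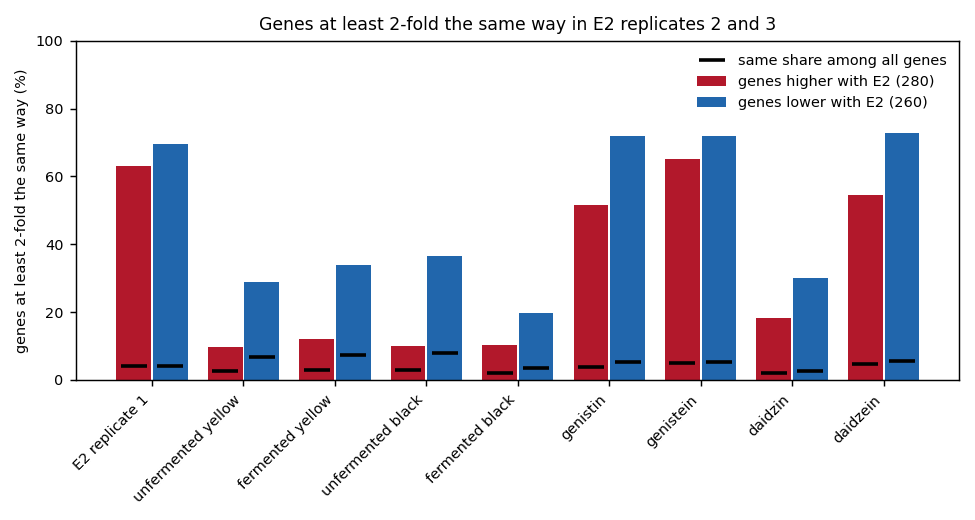
Percentage of genes (vertical axis) past 2-fold the same way in each table (horizontal axis), for the 280 genes at least 2-fold higher (red) and the 260 lower (blue) in E2 replicates 2 and 3; black lines give the same percentage among all genes. E2 replicate 1 stands at 63.2% and 69.6%, genistein at 65.0% and 71.9%, daidzin at 18.2% and 30%, and the extracts at 12.1% or less and 36.5% or less.

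The comparison of each aglycone with its glucoside asked whether the sugar changes the response at the same dose of 10 µM. Daidzein gave more than daidzin on estrogen receptor targets. TFF1 was higher by 1.94 on the log2 scale (95% interval 1.38 to 2.49 from the borrowed E2 spread), GREB1 by 1.62 (1.17 to 2.08), PDZK1 by 1.17 (0.43 to 1.92) and PGR by 0.68 (0.23 to 1.14), with adjusted p over the 11 genes named in advance of 0.00386, 0.00386, 0.0326 and 0.0326 in limma's moderated test. MYC at -0.45 (-0.76 to -0.15, adjusted p = 0.0326) was lower, and CYP1A1 at -1.09 (-2.12 to -0.05) did not pass the adjustment. Of the 44 estrogen-induced genes, 37 were above 0 and 10 at least 2-fold higher, with a median difference of 0.57, and 25 were higher and 3 lower when adjusted over the list alone. The median differences were 0.53 for G2/M and mitosis, 0.70 for cholesterol synthesis, 0.44 for hypoxia and glycolysis (0.29 when centred on the reference genes), -0.34 for estrogen-repressed (mean -0.52), -0.46 for interferon response and -0.49 for immediate-early genes. Adjusted over the list alone, 18 G2/M genes, 10 hypoxia genes and 2 interferon genes were higher, and 8 interferon, 8 estrogen-repressed and 3 immediate-early genes lower, with none called for cholesterol synthesis.

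Genistein and genistin were close on the same targets. The difference was 0.22 for TFF1 (95% interval -0.34 to 0.77), 0.15 for GREB1 (-0.30 to 0.61), -0.14 for PGR (-0.60 to 0.32) and 0.19 for PDZK1 (-0.56 to 0.93). The estrogen-induced median difference was 0.17, and 31 of its 44 genes were above 0. The p53 target list, with FAS at 1.91 with genistein and 1.06 with genistin, had a median difference of 0.45, ribosomal proteins -0.40, cholesterol synthesis -0.22, fibroblast markers 0.74 (mean 0.21, 4 of 6 above 0) and basal and myoepithelial markers 0.51 (7 of 8 above 0). Between the aglycones, genistein minus daidzein was 0.25 for TFF1 (-0.30 to 0.81) and 0.01 for GREB1 (-0.44 to 0.46), with list medians of 0.10 for estrogen-induced, 0.64 for immediate-early and 0.49 for p53 target genes. All 20 immediate-early genes were above 0 in that difference, with EGR2, a growth-response transcription factor gene, at 2.99 with genistein and 0.43 with daidzein. Genes past 2-fold numbered 295 higher and 467 lower for daidzein minus daidzin, 353 and 239 for genistein minus genistin, and 344 and 204 for genistein minus daidzein. With the reference-gene centring, the percentage higher for daidzein minus daidzin went from 38.7 to 24.1. The largest differences among named genes by size alone were in multi-copy or readthrough loci: C1QTNF3-AMACR at 11.92 and TMEM256-PLSCR3 at -10.18 for daidzein minus daidzin, RGPD6 at 5.77 and RPL21 at -11.21 for genistein minus genistin, and HIST1H2AD at 11.84 and RPL21 at -12.87 for genistein minus daidzein.

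The fermentation and bean colour comparisons asked whether processing or source changes what an extract does at 10 µg/ml. No fermented minus unfermented difference on the 4 estrogen receptor targets passed the test: TFF1 was 0.28 (95% interval -0.28 to 0.83) for yellow and -0.20 (-0.75 to 0.36) for black, and GREB1 was 0.12 (-0.33 to 0.58) and 0.18 (-0.28 to 0.63). PGR was 0.28 (-0.18 to 0.74) and 0.01 (-0.45 to 0.47), and PDZK1 was 0.12 (-0.63 to 0.87) and -0.56 (-1.31 to 0.19). MYC was higher with fermented than unfermented yellow by 0.71 (0.41 to 1.01, adjusted p = 0.034 over the 11 genes), and by 0.19 (-0.11 to 0.49) for black. For yellow, 19 of 20 immediate-early genes were above 0 with a median of 0.66, and EGR2 stood at 4.32 with fermented and 2.49 with unfermented yellow; 5 of the 20 were higher when adjusted over the list alone. The estrogen-induced medians were 0.08 for yellow and -0.13 for black, the latter -0.02 when centred on the reference genes.

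Fermented black soymilk stood apart from the other extracts. Against unfermented black, all 23 cholesterol synthesis genes were lower with a median of -0.77, all 35 DNA replication and G1/S genes were lower with a median of -0.32, G2/M genes had -0.28 and hypoxia and glycolysis genes -0.27 (-0.21, -0.16 and -0.16 for the last 3 when centred on the reference genes), while 24 of 28 interferon response genes were higher with a median of 0.57 and all 6 fibroblast markers were higher with a median of 0.90. Adjusted over the list alone, 8 interferon genes, 3 hypoxia genes and none of the cholesterol or cell cycle genes passed. Against fermented yellow, the medians were -0.58 for cholesterol synthesis, -0.36 for G1/S (-0.23 with that centring) and 0.57 for interferon response, and XAF1, an interferon-induced gene, was among the 5 highest genes at 3.45. Between the unfermented extracts, black minus yellow was 0.58 for MYC (0.28 to 0.89, adjusted p = 0.0681), 0.34 for immediate-early and 0.21 for cholesterol synthesis genes, and AREG, the amphiregulin gene, was among the 5 highest at 2.68. Genes past 2-fold numbered 169 higher and 199 lower for fermented minus unfermented yellow, 696 and 143 for fermented minus unfermented black, 617 and 149 for fermented black minus fermented yellow, and 163 and 231 for unfermented black minus unfermented yellow.

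On the 14240 genes tested for E2, 291 genes for fermentation of yellow and 307 for unfermented bean colour were past 2-fold, no more than the 303 to 342 that differences between E2 replicates give. The counts were 730 for fermentation of black, 650 for fermented bean colour, 656 for daidzein minus daidzin, 478 for genistein minus genistin and 445 for genistein minus daidzein. With the borrowed spread, limma called 0, 4, 2, 1, 4, 0 and 0 genes for fermentation of yellow, fermentation of black, genistein minus genistin, daidzein minus daidzin, genistein minus daidzein, fermented bean colour and unfermented bean colour, with 591 to 2990 at an unadjusted p under 0.05. The called symbols were the multi-copy loci RPL21, RGPD6 and NPIPA8, the readthrough symbols BLOC1S5-TXNDC5 and MGC57346-CRHR1, and CUTA.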

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

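All tests in this part were chosen after the values were seen. Removing the sugar went with a different change in the 2 isoflavone families. The difference between aglycone and glucoside in the genistein family minus that in the daidzein family was -1.72 on the log2 scale for TFF1 (95% interval -2.51 to -0.94, adjusted p = 0.0213 over the 11 genes named in advance), from 0.22 for genistein minus genistin and 1.94 for daidzein minus daidzin. For GREB1 it was -1.47 (-2.11 to -0.83, adjusted p = 0.0213), from 0.15 and 1.62. A test of the difference itself, the borrowed-spread t-test with the spread of the 3 E2 replicates, set these results apart, and each isoflavone value is 1 mean over 2 samples. Over all genes that test called 1 gene for this contrast. PGR at -0.82 (adjusted p = 0.0908) and PDZK1 at -0.99 (adjusted p = 0.11) had the same sign without passing. The same test of fermentation between black and yellow soymilk passed for none of the 11 genes. MYC at -0.52 and ERBB2 at 0.53 had the lowest adjusted p of 0.156. The shared control cancels in these differences, and no technical explanation for them was tested. A real difference between the compounds stays open, as does any difference between culture wells or in the uptake or breakdown of daidzin.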

How the results depend on the processing

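No paired analysis was possible beyond the authors' own ratios of 1 E2 library to 1 control library, because the tables hold no values of single control or treated libraries. The E2 test of these ratios was paired in this sense, a fit without that pairing could not be run, and the labels do not say which control each ratio used. The planned minimum expression, pseudocounts, count-based tools, replicate block, levels of at least 5 and leaving out a sample of the other treatments were not run, since the tables hold no levels and, for treatments other than E2, no values of single libraries. The borrowed-spread, robust, readthrough, 11-table and E2-replicate-2-and-3 settings and the rule of 3 times the moderated spread were added after the data were seen. With 1 replicate left out, limma called 0 to 1 genes for E2, where 2 ratios leave fewer degrees of freedom. It called 1 gene at an adjusted p of 0.01 and 2069 at 0.1, and 396 genes, of which 319 were called, were at least 2-fold the same way in all 3. The robust fit (550), both centrings (666 and 874) and the genes with a ratio in all 11 tables (977) gave counts within 1.5 times 673.

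For unfermented yellow, fermented yellow, unfermented black, fermented black, genistin, genistein, daidzin and daidzein in that order, 3616, 3803, 4063, 2893, 3550, 3840, 2543 and 3810 genes were past 1.5-fold and 650, 708, 790, 405, 654, 726, 334 and 677 past 3-fold. At 2-fold and over 3 times the moderated E2 spread, the counts were 892, 1018, 1124, 479, 885, 1049, 351 and 1048. With the borrowed spread 0, 0, 2, 3, 2, 2, 2 and 2 were called. Among genes with a ratio in all 11 tables, 793 were past 2-fold with fermented black and 653 with daidzin, where fewer genes were counted. The other 6 stayed within 1.5 times.

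For fermented minus unfermented yellow, fermented minus unfermented black, genistein minus genistin, daidzein minus daidzin, genistein minus daidzein, fermented black minus fermented yellow and unfermented black minus unfermented yellow, 992, 2176, 1582, 2110, 1546, 1978 and 1036 genes were past 1.5-fold and 83, 230, 166, 220, 152, 186 and 95 past 3-fold. With the spread rule 83, 369, 185, 308, 186, 287 and 103 were left, and with the borrowed spread 0, 4, 2, 1, 4, 0 and 0. Over genes with a ratio in all 11 tables the counts were 244 for fermented minus unfermented yellow, 365 for genistein minus daidzein and 249 for unfermented black minus unfermented yellow, where fewer genes were counted. Leaving out readthrough symbols, keeping date-like symbols, and both centrings kept every count of a treatment or difference within 1.5 times. No symbol was repeated once date-like symbols were left out, so the setting for repeated symbols could change nothing.

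Pearson's r with E2 replicate 3 alone was 0.0649 for unfermented yellow, 0.0546 for fermented yellow, 0.0456 for unfermented black, 0.0525 for fermented black, 0.458 for genistin, 0.481 for genistein, 0.249 for daidzin and 0.423 for daidzein. It was 0.518 for genistin and 0.527 for genistein with replicate 2 alone, and 0.572 for genistein with replicates 2 and 3. These replicates do not share their control with the treatments. Over the estrogen-induced and estrogen-repressed genes together, r was 0.487 for unfermented yellow, 0.555 for fermented yellow, 0.592 for unfermented black and 0.289 for fermented black. It was 0.964 for genistin, 0.939 for genistein, 0.790 for daidzin and 0.958 for daidzein. These lists have medians on opposite sides of 0, and the gap between them adds to this r. Within each list alone the extracts had r of -0.26 to -0.01 (estrogen-induced) and 0.07 to 0.44 (estrogen-repressed). Spearman's rho was 0.474 between E2 replicates 1 and 2 and 0.556 between 2 and 3; the cause was not tested.

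Of the 27 E2 list tests, 3 were lost (cholesterol synthesis, BCL2 family and leukocyte markers) and 1 gained (ribosomal proteins) without replicate 1, and 2 were gained (AhR targets and reference genes) without replicate 3. None changed with either centring or with shared members left out. With means for medians the test itself was not rerun, and no called list changed sign. Centring on the reference genes moved 235 of 405 list medians of treatments and differences and 108 of 315 values of named genes. It turned the sign of 72 of these medians, none above 0.362 in size, and of 10 E2 medians, none above 0.108. It turned 18 values of named genes, up to 0.341. The mean in place of the median moved 90 of the 405 medians and turned the sign of 35, up to 0.424 in size (basal and myoepithelial markers with genistein), and of 2 E2 medians, none above 0.0598. No called value changed sign in any setting.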

Other observations

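The comparison of isoflavones with extracts and the tests of explanations below were chosen after the data were seen, while the E2 list tests were planned. The 4 isoflavone tables were set against the 4 extract tables, in which the shared control cancels. The isoflavones were given at 10 µM and the extracts at 10 µg/ml, and the isoflavone content of the extracts is not known here. Dose therefore cannot be told apart from the kind of treatment in this comparison. Of 13852 genes, limma called 427 higher and 219 lower with the isoflavones. The 4 treatments of each kind stood in for replicates, so the p-values rest on the spread between unlike treatments, not between samples of 1 treatment. A difference between the cultures of the 2 kinds would give such calls too and was not tested. B3GNT6 was higher by 3.29 on the log2 scale (means 4.82 and 1.53, SD 1.28 and 0.32 over 4 treatments each, adjusted p = 0.0269). Among the 10 highest were also KLK11, a kallikrein gene, by 3.39 (isoflavone mean 1.39), ACOX2, a bile acid enzyme gene, by 2.92 (means 1.76 and -1.16), SLC5A8 by 2.88 (2.73 and -0.15), and ABCC11, an efflux transporter gene, by 2.71 (0.12 and -2.59). CRISP3 at -2.83 (means -2.66 and 0.17, adjusted p = 0.013), PLCE1 at -2.41 (-2.56 and -0.16) and CYP4B1 at -1.84 (-1.67 and 0.17) were among the 10 lowest. Of the 646 called genes, the extract mean stood further from 0 in 328 and the isoflavone mean in 318. GREB1 was higher by 2.03 (adjusted p = 0.0262) and PGR by 1.16 (adjusted p = 0.0175), ESR1 was lower at -0.64 (adjusted p = 0.048), and TFF1 at 1.88 (adjusted p = 0.0537) and MYC at -0.75 (adjusted p = 0.0538) did not pass.

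Of 46 estrogen-induced genes, 12 were higher and 1 lower with the isoflavones than with the extracts, or 26 and 2 when adjusted over the list alone (median difference 0.51, camera adjusted p = 3.73e-11, adjusted p = 0.575 with an estimated correlation). Of 21 hypoxia and glycolysis genes 5 were higher and 0 lower, or 13 and 2 when adjusted over the list alone (median 0.46, adjusted p = 0.00023, adjusted p = 0.635 with an estimated correlation). Of 28 interferon response genes 1 was lower and 0 higher, and the same counts held when adjusted over the list alone (median -0.52, adjusted p = 0.0015, adjusted p = 0.743 with an estimated correlation). Of 4 leukocyte markers 2 were higher and 0 lower, or 4 and 0 when adjusted over the list alone (median 0.96, adjusted p = 0.000705, adjusted p = 0.575 with an estimated correlation). Of 8 basal and myoepithelial markers 1 was higher and 0 lower, or 4 and 1 when adjusted over the list alone (median 0.62, adjusted p = 0.0389, adjusted p = 0.635 with an estimated correlation). Of 22 p53 targets 1 was higher and 0 lower, or 3 and 0 when adjusted over the list alone (median 0.32, adjusted p = 0.000406, adjusted p = 0.743 with an estimated correlation). Camera also called the estrogen-repressed list (median -0.27, 1 higher and 2 lower, or 1 and 7 when adjusted over the list alone, adjusted p = 0.0089, adjusted p = 0.743 with an estimated correlation). The growth factor and kinase signalling list was called too (median 0.31, 3 higher and 1 lower, or 8 and 3 when adjusted over the list alone, adjusted p = 0.0384, adjusted p = 0.575 with an estimated correlation), as was the histone list (median -0.17, 0 higher and 1 lower, or 0 and 3 when adjusted over the list alone, adjusted p = 0.01, adjusted p = 0.575 with an estimated correlation). With no gene called, also when adjusted over the list alone, the test passed for G2/M and mitosis (-0.11, adjusted p = 0.0483), immediate-early (-0.37, adjusted p = 0.0369), ribosomal protein (-0.13, adjusted p = 0.0015) and oxidative phosphorylation genes (-0.14, adjusted p = 0.0015), each at adjusted p = 0.861 with an estimated correlation. Centred on the reference genes, the G2/M, histone, ribosomal protein and oxidative phosphorylation medians were -0.05, -0.11, -0.07 and -0.08, and the mean was -0.32 for histones. The DNA replication and G1/S list differed by a median of -0.01 (mean 0.00, 0.06 with that centring, adjusted p = 0.933) and the cholesterol synthesis list by 0.00 (0.06 with that centring, adjusted p = 0.861). A model with further terms called 90 genes higher and 30 lower with the isoflavones, and 0 genes each for fermentation, bean colour, aglycone against glucoside and isoflavone family, with 332, 336, 963 and 745 at an unadjusted p under 0.05 in limma. That model left 2 residual degrees of freedom and had no term for a sugar effect that differs between the isoflavone families. Its 0 calls therefore do not show that these factors have no effect.

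The other 17 lists had these E2 medians over tested genes, with none called by camera: ATF4 and ER stress 0.11, AhR targets -0.20, NRF2 targets -0.16, p53 targets 0.03, ribosome biogenesis and MYC targets 0.08, steroid and isoflavone conjugation 0.06, growth factor and kinase signalling 0.11, oestrogen receptors and cofactors 0.01 and luminal epithelial identity 0.05. Basal and myoepithelial markers had 0.01, fibroblast markers 0.38 (mean 0.01), endothelial markers -0.75, replication-dependent histones -0.14, ribosomal proteins 0.01, oxidative phosphorylation 0.05, snoRNA host and non-coding genes -0.12 and reference genes 0.17. Of these lists, 10 turned sign when centred on the reference genes, none with a median above 0.108 in size. Fry's test passed for 5 of the 27 lists (estrogen-induced, estrogen-repressed, interferon response, hypoxia and glycolysis, and leukocyte markers), and its mixed form for 23.

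The genes that differed between isoflavones and extracts may in part reflect an estrogen-like response to the isoflavones. Of the 640 called genes with a ratio in E2 replicates 2 and 3, 592 (92.5%) had the sign of their mean, against 61.8% among genes not called, and r across 13756 genes was 0.568. In the 35 splits of the 8 tables into groups of 4, only the real one gave as many as 646 genes. The highest other gave 1. The extract tables resemble each other, so mixed splits were bound to call few genes, and the real split was chosen after the values were seen. The splits therefore show that the tables fall into these groups, and do not exclude chance. Among 13733 genes, 111 were called higher and 58 lower in both this comparison and E2, where 10.4 and 4.85 would overlap by chance, and 1 had opposite signs. The difference had the E2 sign in 302 of the 314 genes with the isoflavone mean further from 0 and in 290 of the 326 with the extract mean further from 0, so an action of the extracts on these genes stays open.

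High cell cycle and cholesterol medians and low interferon medians stood in all 4 extract tables, with a signed median of 1.05 over 119 genes. A scaling of whole tables moves all genes alike and is argued against by a gap of at least 1.33 between the high and low lists in each extract table. The single control library behind these tables may account for part of the pattern: E2 replicate 1, made against it, stood 0.262 higher on the same measure than E2 replicates 2 and 3. It cannot be told apart from an effect of the extracts, since no extract table was made against another control. It cannot account for fermented black, which stood at -0.363 from the other 3 extracts while these stood between -0.07 and 0.06 from each other, so a difference between that extract or its cultures and the others stays open.

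For readthrough symbols, values of 16-fold or more in the treatment tables may come from reads shared between overlapping loci. Readthrough symbols reached them in 18 of 58 cases (31.0%), against 57 of 15687 other symbols (0.363%), an odds ratio of 123 (Fisher's exact test, 2-sided p = 6.85e-29). The genes that these symbols join had a median signed log2 ratio of -0.032 over 79 values, with 2 past 2-fold the same way. A change in transcription of those genes is therefore argued against. A change in the readthrough transcript alone need not move them and stays open. The 79 values repeat some loci across tables that share a control. The tables hold no read counts, so how the reads were assigned stays open. This explanation was not tested for the 57 other symbols. Without expression levels, genes at low levels could not be left out of either group.

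For E2, the 3 ratios allow 4 sign patterns, 1 of them the real one, with 673 genes against 0 for the highest other, and these are too few for a share under 0.05. The simulated data for each test held unchanged genes as well, and 12 of the 138 called by the E2 test were among these, as were 12 of 100 for the borrowed-spread test of 1 treatment, 7 of 112 for that of a difference and 6 of 170 for isoflavones minus extracts. The first 3 shares were above the 0.05 that the adjustment sets.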
